A study of Mus musculus with 8 samples.

How the data were processed

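Total RNA was measured from cranial mesenchyme of wild-type C57BL/6 mouse embryos at E12.5. Per the labels' protocols, apical and basolateral parts of the head were dissected and treated with dispase at 3 U/ml and 37 C for 10 min, and the surface ectoderm and the brain were then taken off. Tissue of 4 to 5 embryos was combined for each of the 8 samples, which were 4 pools of early migrating mesenchyme (EMM) and 4 pools of supraorbital mesenchyme (SOM). RNA was extracted with a column kit and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Whether EMM and SOM pools were cut from the same embryos is not given in the sources used here.

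The submitters' processing notes name bcl2fastq, STAR and DESeq2, without versions, and the mouse build mm10. The gene annotation, the read counter and whether counting used the strand are not given in the sources used here. The authors deposited a single table of 23420 genes. Its library columns hold the signal of each gene as a normalized count, which per the file headers and the values is a read count divided by a size factor per library. The same table holds the mean normalized count, and the authors' log2 fold change with its standard error. It also holds the authors' Wald score and, from the deposited comparison, the p-value and adjusted p-value of each gene. The sign of the deposited log2 fold change was checked against the group means, and positive values mean higher in EMM. All 8 library columns were matched to samples by their titles.

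In every library, 100% of the deposited normalized counts were whole multiples of the smallest value above 0 in that column, within 1 ppm, so the reads behind them were recovered by division. The recovered totals ran from 12.7 to 22.4 M reads in EMM and from 16.8 to 33.7 M in SOM. A count of 3 reads over the summed libraries of a group was used as the floor for genes with no reads. Within a single library, 3 reads came to between 1.91 and 5.42 normalized counts. Intervals and floors cover counting error only, since the reads carried no molecular identifiers.

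The design was set before the data were examined, and for a normalized unit it named limma in place of a count test. Genes with a normalized count of at least 10 in at least 4 libraries were kept, which left 14249, and 4477 genes were at 0 in all 8 libraries. Values were taken as log2(normalized count + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, all 8 libraries and no covariate. Differences are SOM minus EMM on that scale, which understates the change of genes with low values. Benjamini-Hochberg adjusted p-values were called at 0.05, and 2-fold counts used the fitted difference. The p-values measure the spread between pools.

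Before the data were examined, 27 gene lists were fixed for the skeletal, patterning, signalling and matrix genes of the head and for other cell types that the dissection could hold. Members were matched by symbol and older symbols. 2 red blood cell genes, Hbb-bt and Ahsp, had no match and were not analysed here. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. Camera with an estimated correlation and fry were run beside it. Counts of members adjusted over the list alone equalled the counts over all genes in every list but the mesenchymal transcription factor list and the immediate early list.

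Genes were named by a rule fixed before the data were examined. It took 12 study genes, picked with knowledge of the study. It then took, in each direction, the 12 genes with the largest fitted difference among those with an adjusted p below 0.05, no overlap between the groups and a mean of at least 100 in the higher group. Last, it took from each list the 3 members per direction with the lowest adjusted p below 0.05, or the member with the highest mean where none passed. This gave 159 genes, all past the threshold, 153 of them without overlap between the groups. Coordinates came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Of the 159 genes, 48 share exonic bases with another annotated gene, so that reads of the pair cannot be told apart without the strand.

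The fit was tested on simulated data in which 200 genes were changed by known folds between SOM and EMM. It recovered 80.6% of the 1.5-fold changes, 90.9% of the 2-fold changes and 100% of the 4-fold changes among 14130 genes run, and called 12 of 13931 unchanged genes. Camera called 0 of 27 random lists there. The simulated genes varied independently of each other and all but 200 were unchanged, whereas 72.1% of the tested genes were called in the data. These runs therefore do not show how camera behaves when list members are correlated. Nor do they show how the scaling behaves when most genes change. Libraries of a group were compared before averaging. Their chi-square per degree of freedom lay between 3.71 and 19.2, so that no pair looked like a library deposited 2 times, and their log2 values correlated across genes at r between 0.990 and 0.995.

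The alternatives were DESeq2 1.42.0, edgeR 4.0.16 quasi-likelihood and limma-voom tests on the recovered reads, upper quartile scaling, no filter and a filter at 50, pseudocounts of 0.5 and 5, an adjusted p of 0.01, each library left out in turn, the replicate number as a block, and hemoglobin genes removed. Leaving out 1 library used a filter of at least 10 in at least 3 libraries. After the data were seen, 3 libraries judged to stand apart from their groups, EMM replicates 2 and 3 and SOM replicate 4, were also left out together. No rule for this choice was set beforehand. That fit kept only EMM replicates 1 and 4 and SOM replicates 1 to 3, with a filter of at least 10 in at least 2 libraries. Figures were drawn with matplotlib 3.10.9.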

Results

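The transcriptomes of 2 regions of the mouse embryonic head mesenchyme were profiled at E12.5, the supraorbital mesenchyme above the eye (SOM), known to hold the primordia of the skull roof bones, and the early migrating mesenchyme (EMM). Each group had 4 libraries, each from a pool of 4 to 5 embryos. EMM replicates 1 to 4 held 22.4, 12.7, 22.0 and 17.3 M gene-assigned reads, and SOM replicates 1 to 4 held 16.8, 30.1, 33.7 and 32.3 M, so that 3 of the 4 SOM libraries were deeper than any EMM library. The comparison asked which genes differ between the supraorbital tissue and the early migrating tissue. All values below are normalized counts, given as mean ± SD with n = 4 libraries per group.

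The bone genes Alpl and Sp7 were higher in SOM and the LIM homeobox gene Lmx1b was higher in EMM. Alpl, which encodes the alkaline phosphatase of mineralizing tissue, stood at 1622 ± 455 in SOM against 167 ± 20.4 in EMM, and Sp7, a transcription factor required for osteoblasts, was 6.95-fold higher in SOM, at 537 ± 138. Lmx1b stood at 1128 ± 37.2 in EMM against 128 ± 22.2 in SOM, an 8.82-fold difference. Across the genome, limma with Benjamini-Hochberg adjustment called 5149 genes higher in EMM and 5129 higher in SOM, together 72.1% of the 14249 tested. Differences of at least 2-fold were more often toward EMM, with 1564 genes against 739 in SOM. The first principal component held 85.4% of the variance and separated the groups, and the 4 libraries of each group lay apart from the other 4 in 9421 genes (66.1%, where chance gives 2.86%). With a filter at 50 normalized counts the 2-fold count in SOM was 455. In the authors' deposited table, 5201 genes were higher in EMM and 5009 higher in SOM at the same threshold.

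Of the 12 study genes, known regulators and markers of skull and head mesenchyme, 6 were higher in EMM and 6 in SOM. They were picked with knowledge of the study, so their counts are not independent evidence of a direction. The homeobox genes Msx1 and Msx2 were higher in EMM, with log2 differences (SOM minus EMM) of -2.22 (SE 0.11) and -2.05 (SE 0.06), and Msx2 stood at 9034 ± 279 against 2192 ± 227. Foxc1, a forkhead gene of the meninges and skull base, was higher in EMM at 5477 ± 249 against 1680 ± 241. Alx4 was 1.46-fold higher in EMM. Dlx5, a homeobox gene of early osteoblasts, was higher in SOM by 3.15 on the log2 scale (SE 0.10), and Runx2, the master regulator of the bone lineage, by 0.66 (SE 0.09), at 2632 ± 310 against 1668 ± 155. Twist2 was 2.05-fold and Twist1 1.25-fold higher in SOM. The adjusted p of limma was at most 0.000459 for 11 of these genes. Tfap2b had 751 ± 163 in EMM and 427 ± 134 in SOM with overlapping libraries (limma adjusted p = 0.0165), and its adjusted p was 0.163 without EMM replicates 2 and 3 and SOM replicate 4, the highest of its alternatives, which went down to 3.04e-07. On GRCm38, Lmx1b lies on chromosome 2 from 33560965 to 33640511, Alpl on chromosome 4 from 137741733 to 137796384, and Runx2 on chromosome 17 from 44495987 to 44814797, where it shares exonic bases with the antisense gene Runx2os1.

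**Figure D1:**
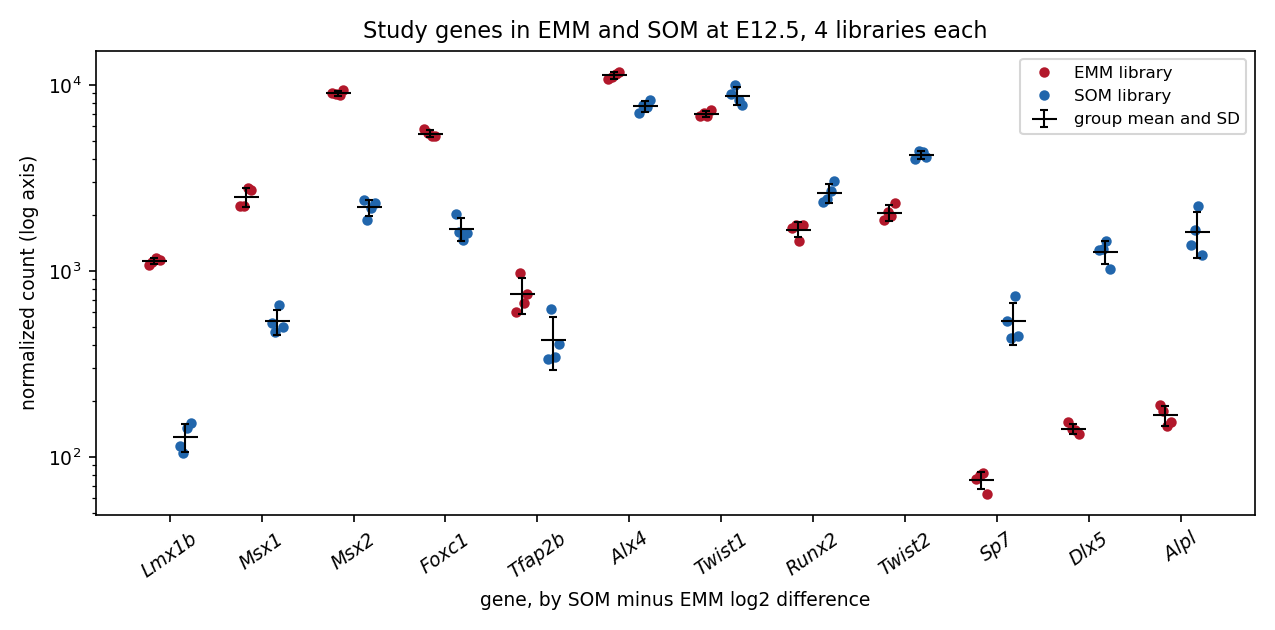
Normalized counts (log axis) of the 12 study genes in each EMM (red) and SOM (blue) library, with bars for the mean and SD of 4 libraries. Lmx1b lies near 1128 in EMM and 128 in SOM, Alpl near 167 in EMM and 1622 in SOM, and the Tfap2b libraries of the groups overlap.

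Among the genes with the largest differences toward SOM, Olig2, a bHLH factor best known from the spinal cord and brain, stood at 547 ± 98.5 in SOM, with 2881 reads there and 1 read in EMM, a ratio of 1760 (95% counting interval 316 to 69560). It lies on chromosome 16 from 91225457 to 91228677. Sox10, a factor of neural crest glia, stood at 513 ± 46.4 against 4.35 ± 1.69. Igfbp5, a secreted binding protein of insulin-like growth factors, rose to 14587 ± 1562 from 392 ± 97.1. The BMP family ligand Gdf6 was higher by 6.12 on the log2 scale, the synaptic gene Doc2b by 7.41, and Gng4, Sp9 and Dlx6 by 5.89, 5.34 and 5.24. The cartilage gene Matn1 had 3 reads in EMM and 875 in SOM, a ratio of 178 (interval 60.8 to 866), with a wide SOM spread of 189 ± 167, and its log2 difference was 6.10 with all libraries and 6.87 without SOM replicate 2. Irx1 and Shisa3 had log2 differences of 4.92 and 5.70, which were larger without EMM replicate 2, at 5.74 and 6.42, and that of Shisa3 was 5.11 without EMM replicate 4. The adjusted p of limma was at most 0.00218 for these genes.

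Among the genes with the largest differences toward EMM, the bicarbonate transporter gene Slc4a10 had 572 reads in EMM and 1 read in SOM, a ratio of 936 (95% counting interval 167 to 37036). The calcium-binding protein gene Calb2 stood at 452 ± 50.1 against 2.97 ± 1.36, and Cp, which encodes the copper carrier ceruloplasmin, at 1693 ± 164 against 17.3 ± 1.24. The myosin gene Myh2 had a log2 difference of -6.25, and C1qtnf3 and the thyroid hormone enzyme gene Dio2 had differences of -6.20 and -5.81. Cnn1, which encodes calponin of smooth muscle, had 1326 ± 146 in EMM, with a log2 difference of -4.94. Cntnap4, Gabbr2, Nell1, A2m and Diras2 had differences between -5.93 and -5.18. The adjusted p of limma was at most 5.91e-07 for these 12 genes.

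Bone lineage genes moved in both directions. Of 26 measured members, 17 were higher in SOM, 8 in EMM and 1 did not pass. Panx3 rose in SOM by 3.94 and Dlx6 by 5.24 on the log2 scale. Spp1, which encodes the matrix protein osteopontin, was higher in EMM at 527 ± 61.0 against 58.8 ± 9.76, as was the macrophage gene F13a1 (-2.94), and so was Sparc at 73622 ± 4796 against 29822 ± 1534. Among 19 cartilage genes, 13 were higher in SOM, 3 in EMM and 3 did not pass. Without EMM replicates 2 and 3 and SOM replicate 4 the count higher in SOM was 8, and with no filter on low values 12 of 23 were higher in SOM and 5 in EMM. Sox6 rose in SOM by 1.76 and Sox5 by 0.87, while the matrix genes Col11a1, Hapln1 and Fmod were higher in EMM, at -1.70, -1.93 and -2.80. Camera called neither list (adjusted p = 0.105 for bone and 0.0871 for cartilage), though without SOM replicate 2 the cartilage list had an adjusted p of 0.0109, the lowest of its alternatives, which reached 0.857.

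Transcription factors that pattern the head mesenchyme split between the regions. Of 63 measured, 32 were higher in SOM, 24 in EMM and 7 did not pass, with 25 higher in EMM when adjusted over the list alone. Alx1, a homeobox gene needed for the frontonasal skull, stood at 6027 ± 517 in SOM against 748 ± 57.2 in EMM, Tbx15 at 10652 ± 854 against 1993 ± 92.8, and Eya1 was higher in SOM by 2.65. The zinc finger genes Zic1 and Zic4 were higher in EMM, at 10764 ± 358 against 1340 ± 148 and 2951 ± 153 against 116 ± 10.1, and share exonic bases with each other. Tbx18 was higher in EMM, at -2.33. Of 26 genes known for premature fusion or defects of skull sutures, 13 were higher in SOM, among them Fgfr2 (0.70) and the retinoic acid degrading enzyme gene Cyp26b1 (2.88), 9 in EMM, among them Efnb1 (-1.28), and 4 did not pass. Camera called neither list (adjusted p = 0.458 and 0.823), and the suture list had a median of 0.14, a mean of -0.04, a camera direction toward SOM and a fry direction toward EMM.

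Genes of the collagen matrix, the meninges and axon guidance were mostly higher in EMM. Of 50 collagen and matrix genes, 44 were higher in EMM, 3 in SOM and 3 did not pass, and collagen genes took 5.25% to 5.92% of reads in EMM libraries against at most 2.61% in SOM libraries. Pericyte and smooth muscle genes, 11 of 12 with a median of -2.11, and macrophage genes, 19 of 20 with a median of -1.77, were also higher in EMM. The basement membrane genes Nid1, Lama2 and Col4a5 had differences of -1.81, -2.01 and -2.03, while Col25a1 (3.48), Col15a1 (0.93) and Postn (0.48) were the 3 higher in SOM. Camera gave adjusted p = 1.87e-10 for this list, and adjusted p = 0.485 with an estimated correlation. Of 31 meninges genes, 22 were higher in EMM, such as Angptl2 (-1.43) and Serping1 (-1.94), 3 in SOM, namely Mgp (1.45), Nnat (0.61) and Col15a1, and 6 did not pass. Camera gave adjusted p = 5.03e-05 there, and adjusted p = 0.485 with an estimated correlation. Of 45 guidance genes, 28 were higher in EMM, such as the Eph receptor gene Epha7, at 10599 ± 572 against 1087 ± 118, and Efnb2 (-2.07). A further 10 were higher in SOM, such as the netrin receptor gene Dcc (3.84) and Sema6a (1.27), and 7 did not pass. Camera gave adjusted p = 0.00881, and adjusted p = 0.569 with an estimated correlation.

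Cell division genes were higher in SOM. Of 37 measured, 35 were higher in SOM, 1 in EMM and 1 did not pass, with a list median of 0.52. The replication helicase gene Mcm7 rose by 1.09, the nucleotide synthesis gene Rrm2 by 0.95, Tyms stood at 2165 ± 111 in SOM against 1084 ± 49.5 in EMM, and the cyclin gene Ccne2 was the member higher in EMM, at -0.43. Camera gave adjusted p = 1.37e-08 for this list, and adjusted p = 0.485 with an estimated correlation. Red blood cell genes, whose share of reads was higher in EMM, moved the other way.

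Signalling genes split by pathway member. Of 47 WNT genes, 27 were higher in EMM, such as the antagonist gene Frzb, at 1861 ± 124 against 97.9 ± 12.9, the ligand gene Wnt6 (-4.03) and Dkk2 (-1.87). Another 12 were higher in SOM, such as Rspo3 (3.23), Lef1 (2.07) and Tcf7l2 (1.10), and 8 did not pass. Of 17 Hedgehog genes, 10 were higher in SOM, such as Hhip (2.57) and Boc (1.46), 5 in EMM, such as Cdon, at 11314 ± 257 against 2859 ± 228, and Scube2 (-2.32), and 2 did not pass. Of 27 FGF genes, 15 were higher in SOM, such as Fgf7 (2.89) and Fgf10 (2.29), 6 in EMM, such as Fgfbp1 (-3.20) and Il17rd (-0.80), and 6 did not pass. Of 44 BMP and TGF-beta genes, 16 were higher in SOM, such as Bmp2 (2.01) and Bmper (3.99), 17 in EMM, such as Bmp4 (-1.17) and Tgfb2 (-2.01), and 11 did not pass. Of 18 retinoic acid genes, 7 were higher in SOM, such as Aldh1a3 (2.08) and Rxrg (2.60), 8 in EMM, such as Crabp2 (-1.10) and Stra6 (-1.15), and 3 did not pass. Of 20 genes of dermal fibroblast progenitors, 8 were higher in SOM, such as En1 (2.06), 11 in EMM, such as Lum (-1.28) and Thbs1 (-1.91), and 1 did not pass. Camera called none of these 6 lists, with adjusted p between 0.0816 and 0.962, while fry called the WNT, Hedgehog and FGF lists at an adjusted p of at most 0.00210. The BMP list had a median of -0.05 and a mean of 0.20, and the dermal list a median of -0.31 and a mean of 0.23, so that median and mean differed in sign, and fry gave each a direction opposite to that of camera.

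**Figure D2:**
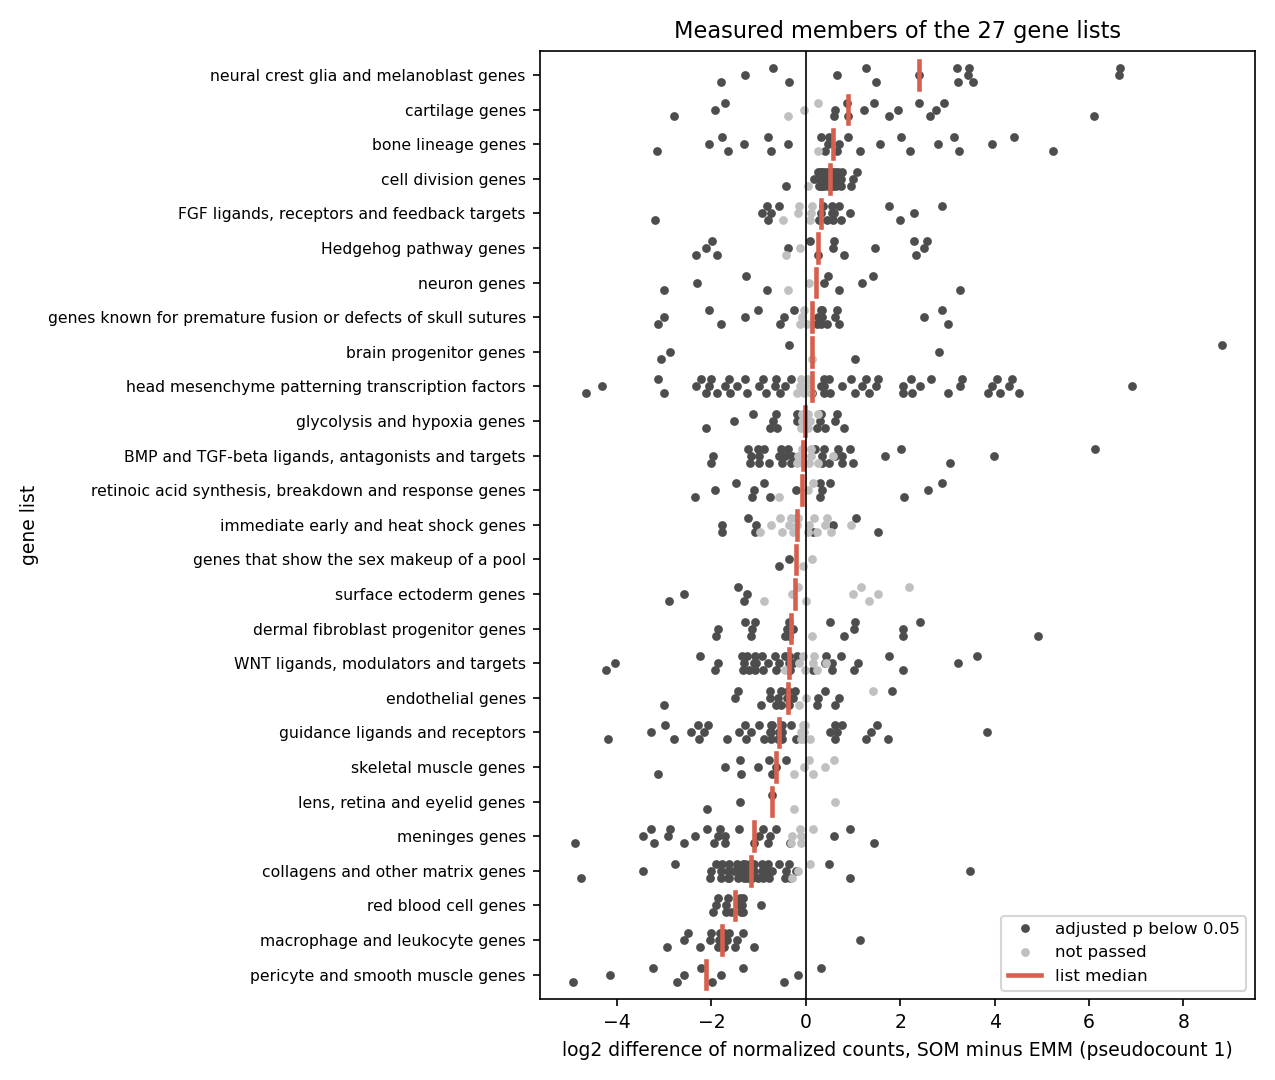
Log2 differences (SOM minus EMM, pseudocount 1) of the measured members of the 27 gene lists, each point a gene, dark where the adjusted p was below 0.05, with red bars at list medians. The medians run from -2.11 for pericyte and smooth muscle genes to 2.40 for neural crest glia and melanoblast genes.

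Most genes of the macrophage list, the pericyte and smooth muscle list and the red blood cell list were higher in EMM, and most neural crest glia markers were higher in SOM. Of 27 actin cytoskeleton and smooth muscle genes, chosen after the main results were seen, 23 were also higher in EMM and none in SOM. Whether the number of pericytes differed was therefore not tested. Of 20 macrophage genes, 19 were higher in EMM, such as Csf1r, the receptor gene of macrophage growth, at 3044 ± 232 against 638 ± 50.1, and F13a1 (-2.94), and Cd83 was higher in SOM (1.14). Of 12 pericyte and smooth muscle genes, 11 were higher in EMM, such as Acta2, the smooth muscle actin gene, at 38221 ± 2811 against 2167 ± 238, and Tagln (-3.24), and Cspg4 was higher in SOM (0.33), a call lost without EMM replicate 2, 3 or 4 or SOM replicate 1, 3 or 4 and without EMM replicates 2 and 3 and SOM replicate 4 together. All 14 measured red blood cell genes were higher in EMM, such as Alas2 (-1.58) and Rhag (-1.90), 11 of them also without EMM replicates 2 and 3 and SOM replicate 4, and hemoglobin genes took 0.646% to 1.78% of reads in EMM and 0.379% to 0.449% in SOM. Of 15 glia and melanoblast genes, 11 were higher in SOM, such as Erbb3 (3.55), and 4 in EMM, such as Ednrb (-1.80) and Kit (-1.28). Foxd3 had 0 reads in EMM and 99.9 ± 5.10 normalized counts in SOM, at least 107.55-fold higher with a floor of 3 reads over the summed EMM libraries. Camera gave adjusted p = 3.41e-08 for macrophages, 0.000919 for pericytes, 0.00713 for red blood cells and 0.0220 for glia and melanoblasts. With an estimated correlation these were adjusted p = 0.485, 0.569, 0.653 and 0.485 in that order. The glia call was also lost with a filter at 50 (camera adjusted p = 0.121), without EMM replicate 1 (0.0586) and without SOM replicate 1 (0.0540), in a range of alternatives from 9.60e-08 to 0.485.

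Of 24 endothelial genes, 15 were higher in EMM, such as Emcn (-1.49) and Lyve1 (-3.00), 6 in SOM, such as Flt4 (0.69) and Robo4 (0.40), and 3 did not pass. Of 15 skeletal muscle genes, 9 were higher in EMM, such as Myh8 (-3.13), at 361 ± 132 in EMM, none in SOM, and 6 did not pass. In SOM, 2 muscle genes were higher without EMM replicate 3 or with no filter on low values, and 1 without SOM replicate 2 or with edgeR, upper quartile scaling or a pseudocount of 5, and with a filter at 50 the 3 measured were higher in EMM. Of 14 surface ectoderm genes, 5 were higher in EMM, such as Krt8 (-2.89) and Cdh3, at 3515 ± 210 against 1488 ± 135, none in SOM, and 9 did not pass. The mean of this list on the log2 scale was 4.75, 6.37, 5.72 and 4.96 in EMM replicates 1 to 4. In SOM libraries it lay between 4.94 and 5.56, within the EMM range. In SOM, 4 ectoderm genes were higher without EMM replicate 2 or with limma-voom, 2 with no filter, and 1 without EMM replicate 3 or with edgeR, upper quartile scaling, a pseudocount of 5 or the replicate block, and without EMM replicates 2 and 3 and SOM replicate 4 the count was 5 in each direction, and camera called the list with a filter at 50 (adjusted p = 0.0489, in a range of alternatives from 0.000730 to 0.925). Of 12 neuron genes, 6 were higher in SOM, such as Stmn2 (3.26) and Tubb3 (1.20), 4 in EMM, such as Syt1 (-3.02), and 2 did not pass, with a median of 0.23 and a mean of -0.02, and with a filter at 50 the counts were 5 and 2 of 7. Of 7 brain progenitor genes, 3 were higher in SOM, such as Emx2 (2.81), 3 in EMM, and 1 did not pass, with a median of 0.13. With no filter on low values 5 of 22 were higher in SOM and 10 in EMM, with a median of -0.43, without SOM replicate 1 the counts were 3 and 5 of 9, and with a filter at 50 they were 3 and 1 of 4. Of 5 eye genes, 3 were higher in EMM, such as Cryab (-2.10), none in SOM, and 2 did not pass. With each library left out in turn, 1 to 3 eye genes were higher in SOM in every case but 1, SOM replicate 1, against 2 in each direction of 7 measured without EMM replicates 2 and 3 and SOM replicate 4, and with no filter 3 of 18 were higher in SOM and 5 in EMM. Camera called none of these 6 lists, with adjusted p between 0.128 and 0.658.

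Immediate early and heat shock genes varied between libraries of a group. Of 27 measured, 4 were higher in SOM, such as Myc (1.54) and Klf4 (1.06), 6 in EMM, such as Klf6 (-1.78) and Hspb1 (-1.77), and 17 did not pass, with 2 higher in SOM when adjusted over the list alone, and also 2 without EMM replicate 1 or SOM replicate 2. The list mean on the log2 scale was 8.93 in SOM replicate 1 and 10.50 in SOM replicate 4. Of 25 glycolysis and hypoxia genes, 7 were higher in SOM, such as Gapdh (0.62) and Pkm (0.67), 9 in EMM, such as Ndrg1 (-1.53), and 9 did not pass. Of 4 Y-linked genes, Ddx3y (-0.57) and Uty (-0.36) were higher in EMM and 2 did not pass, while 1 was higher in SOM without EMM replicate 1 or SOM replicate 3 or with upper quartile scaling. Camera called none of these 3 lists, with adjusted p between 0.643 and 0.771. Of all 27 lists, camera called 8, none of which was called with an estimated correlation, and 12 of the 16 splits that exchanged 1 library between the groups gave 8 or more, up to 11, while the 18 splits with 2 libraries of each region on a side gave 1 to 7.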

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

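The tests of nerve-associated glia, of the share of mesenchyme and of Spp1 in macrophages were chosen after the results were seen, and the 3 patterns weighed and the 29 brain genes were picked after the main results were seen, the brain genes before their own values were. Chance was weighed by refitting all 35 splits of the 8 libraries into 4 and 4. Only 1 split, the real one, gave 10278 genes past the threshold, and the highest of the others gave 0. Every other split put libraries of both regions on each side. This adds the regional difference to the spread, so their low counts were fixed by the design. The rank of the real split argues against chance only as far as 35 splits allow. The same held for the 2303 genes at least 2-fold apart, which 1 split reached, with 0 in the highest of the others. For the 8 lists called by camera, 13 of the 35 splits gave as many and the highest of the others gave 11, so that this count did not exclude chance. The 12 others with as many were all among the 16 splits that exchanged 1 library between the groups and so kept part of the difference between EMM and SOM. The 18 splits with 2 libraries of each region on a side gave 1 to 7 lists.

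Olig2 and Sox10 were among the largest differences toward SOM, at 8.83 and 6.64 on the log2 scale. Brain tissue left on the SOM mesenchyme was weighed with 29 brain genes. Their SOM means had a median of 3.47 normalized counts, with 6.01 in the highest library. Both lay below a limit of 54.7, set from the Olig2 mean of 547. However, 7 of the genes lay above that limit, among them Pou3f3 (945 in SOM, 146 in EMM), Irx3 (3196 and 1596) and Ptprz1 (93.6 and 27.7). Only 14 of the 29 passed the filter, 4 of them higher in SOM and 7 in EMM, with a median difference of -0.48. The tested brain genes as a set were therefore not higher in SOM. Brain tissue that expresses few of the 29 genes cannot be excluded by this median. Cells of the oligodendrocyte lineage were argued against by Olig1, at a SOM mean of 1.01 and at most 2.80 in a library. More nerve-associated glia in SOM stays open, because the 8 other glia genes differed by a median of 3.33, also with Foxd3 at its bound, against 3.32 for the share of the Sox10 difference set as the limit, but Fabp7 was lower in SOM, at -0.35, a call lost without EMM replicate 4 (adjusted p = 0.0938) or SOM replicate 2 (0.0697), 3 (0.0644) or 4 (0.0508). A regional difference between SOM and EMM cells in Olig2 stays open and was not tested.

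Macrophage and red blood cell genes were higher in EMM, with list medians of -1.77 and -1.50. A lower share of mesenchyme in EMM, acting alone, would raise every other cell type alike. As the only cause it was argued against by 7 lists of other cell types. Their medians spanned 4.50 on the log2 scale, beyond the larger interquartile range of 3.29. They ran from pericytes and smooth muscle at -2.11 to glia and melanoblasts at 2.40. The outermost lists decide this test. It cannot tell whether a lower share took part beside a separate difference in glia or smooth muscle genes. More blood left in EMM was argued against for the macrophage genes, since within groups their mean did not follow the red blood cell mean, with a slope of -0.133 (95% interval -0.229 to -0.0377) against 1.12 for the ratio of the group differences. The slope was -0.0952 (95% interval -0.445 to 0.255) without EMM replicates 1 and 3, the libraries farthest from the median of their group, still below the limit of 0.561, which is the ratio divided by 2. A larger number of macrophages in EMM tissue stays open as a biological difference and was not tested.

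Bone list members moved in both directions, 17 toward SOM and 8 toward EMM. A scaling between libraries moves all members alike. The spread between members, with quartiles of -0.65 and 2.15 on the log2 scale, cannot come from scaling alone. It stays the same under any shift common to all members, so it does not say whether both directions came from scaling. Whether scaling took part in which members lay toward EMM cannot be told apart. The 5 other scalings and count tests run, with 8 members toward EMM at the lowest, moved the list median by at most 0.0349. The smallest difference of a called member was 0.331. Whether Spp1 was carried by macrophages cannot be told apart from a mesenchymal difference, because its log2 difference lay beyond the largest of a macrophage gene by -0.21 with a standard error of 0.147. A difference in osteogenic stage between the regions stays open and was not tested.

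In 17 of 377 groups of 4 libraries (4.51%), 1 library lay far from the others by its gap over the range, where chance gives about 1 in 20 groups. The values that follow are that ratio. EMM replicate 3 was lowest for Fstl1 (0.913) and Sparc (0.877) and highest for Flt4 (0.878), Tyms (0.833) and Zic1 (0.876). EMM replicate 2 was highest for Irx1 (0.892), at 74.1 normalized counts against 10.8 in the next library, and for Shisa3 (0.855). EMM replicate 1 was lowest for Hk1 (0.884) and highest for the Y-linked list mean (0.874) and for Olig2 (1), which had its 1 EMM read there. EMM replicate 4 was highest for the glycolysis and hypoxia list mean (0.840). SOM replicate 4 was highest for the FGF (0.877) and guidance (0.859) list means and for Slc4a10 (1), a single read. Among the other SOM libraries, replicate 1 was highest for Fabp7 (0.856), replicate 2 lowest for Cd83 (0.950) and replicate 3 highest for Fgf7 (0.888).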

How the results depend on the processing

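Leaving out EMM replicates 2 and 3 and SOM replicate 4 together was chosen after the data were seen. The 4 counts of genes stayed within 1.5 times under every alternative but 1, the filter at 50, where 455 genes were at least 2-fold higher in SOM and fewer genes (12337) were tested. With 1 library left out they ran from 4962 to 5269 (higher in EMM), 4885 to 5097 (higher in SOM), 1560 to 1651 and 748 to 791 (at least 2-fold), and at least 94.5% of the 10278 calls were kept in direction. The edgeR, DESeq2 and limma-voom tests shared 10154, 9927 and 10135 of those calls, with none opposite. The deviations of same-numbered libraries correlated weakly (0.126, 0.00993, 0.0419 and -0.0199 for numbers 1 to 4). EMM replicate 1 and SOM replicate 1 correlated best with each other, and EMM replicate 2 best with SOM replicate 2. Not every library correlated best with its own number. With 4 libraries per group this leaves shared embryos or batches open. With the replicate block 5146 and 5103 genes were called, 1563 and 748 at least 2-fold, and 8 lists. Of 3010 values of named genes under alternatives, 2987 kept direction and side, 23 lost the threshold, all in Crybb1, Cspg4, Fabp7, Jund and Tfap2b, and 0 turned.

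Camera called 7 to 9 lists with 1 library left out, 0 with an estimated correlation and 21 with fry. The fry test does not compare a list with other genes. Directions that turned belonged to lists that camera did not call. The BMP list turned with no filter (adjusted p = 0.882), without EMM replicate 3 (0.941), without SOM replicate 4 (0.762), without the 3 libraries (0.789) and with fry (0.516). Over the leave-outs of 1 library its adjusted p ran from 0.762 to 0.988. The dermal list turned without EMM replicate 2 (0.938), EMM replicate 4 (0.988) or SOM replicate 3 (0.984) and with fry (0.104), with 0.819 to 0.988 over those leave-outs. The brain progenitor list turned with no filter (0.671) and, like the immediate early list, without SOM replicate 1 (0.950 each), with leave-outs from 0.486 to 0.984 and from 0.287 to 0.950. The retinoic acid list turned with the filter at 50 (0.959) and the suture list with fry (0.0208). The cause was not tested. Depth limited EMM more, where 1 read was worth up to 1.81 normalized counts.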

Other observations

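The gene families in this part were chosen after the main results were seen, and their genes after their values were seen. All 5 measured Iroquois genes were higher in SOM, such as Irx5 (1.71) and Irx6 (5.52), all 5 measured Dlx genes, such as Dlx1 (3.96) and Dlx2 (4.37), and all 5 measured Hox genes, such as Hoxd4 (3.75), at 19.5 ± 3.77 in SOM. The filter kept Irx2, Irx6, Dlx1, Dlx2, Dlx6, Hoxd3, Hoxd4 and Hoxd9, with EMM means under 10, through their SOM values, so that their direction and the tests of these families are partly set by the filter. The same holds for Irx1, which had 3.07, 74.1, 8.36 and 10.8 normalized counts in EMM replicates 1 to 4. The measured Hox genes were all of the Hoxd cluster, and the other 34 of 39 Hox genes in the table were not measured. Of 15 Sox genes, 9 were higher in SOM, such as Sox11 (2.05), and 4 in EMM, such as Sox4 (-0.66). Of 27 Fox genes, 11 were higher in SOM and 13 in EMM. Camera with Benjamini-Hochberg adjustment over 15 families, not all of which are given here, gave adjusted p = 0.00534 for Iroquois, 0.00275 for Dlx, 0.0625 for Hox, 0.0857 for Sox and 0.924 for Fox. With an estimated correlation the first 2 were adjusted p = 0.350 and 0.117.

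Of 27 actin cytoskeleton and smooth muscle genes, 23 were higher in EMM and none in SOM, such as Actg2, at 2333 ± 194 against 143 ± 30.9, Myl9 (-1.75) and Tpm1 (-1.24), while Cnn3 had 15738 ± 425 and 14991 ± 579. Of these genes, 4 (Acta2, Cnn1, Myh11 and Tagln) also belong to the pericyte and smooth muscle list, whose median was -2.11. Of 23 MHC class I and interferon response genes, 16 were higher in EMM, such as Bst2 (-1.31) and Usp18 (-2.74), and Ifit2, Ifitm1 and Ifitm2 in SOM, while 19 of 20 macrophage and leukocyte genes were higher in EMM, with a median of -1.77. Of 76 ribosomal protein genes, 72 were higher in SOM and none in EMM, with a median of 0.48. Of 256 solute carrier genes, 132 were higher in EMM and 53 in SOM. Camera gave adjusted p = 5.02e-09, 0.00275, 3.09e-14 and 0.00246 for these 4 families, and with an estimated correlation adjusted p = 0.198, 0.377, 0.377 and 0.117. Camera called none of the 5 families that follow, with adjusted p between 0.169 and 0.751. In these, 8 of 28 imprinted genes were higher in SOM and 9 in EMM, 5 of 17 cadherin genes in SOM and 8 in EMM, such as Cdh10 (-4.48), with a median of 0.10 but a camera direction toward EMM, and 9 of 54 protocadherin genes in SOM and 23 in EMM, such as Pcdh7 (-2.42). For cholesterol synthesis, 4 of 19 genes were higher in SOM and 10 in EMM, and for the brain genes 4 of 14 tested and 7.

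Xist, the RNA of the inactive X chromosome, stood between 0 and 4.01 normalized counts in the 8 libraries and Tsix at 0, while the Y-linked gene Kdm5d stood between 900 and 1117. The sex of the pooled embryos, and whether the counting kept Xist reads, are not given in the sources used here.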
